A study of Drosophila melanogaster with 6 samples.

How the data were processed

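Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for Insensitive (Insv), a BEN domain protein of Drosophila, in Kc167 cells, a cell line derived from fly embryos. The labels give 3 ChIP samples and 3 input samples, the input being DNA of the same kind of chromatin without immunoprecipitation. The antibody was a rabbit polyclonal serum raised against Insv and, per the labels, was pre-adsorbed with fly embryos before use. Per the labels' protocols, cells were cross-linked with formaldehyde and the chromatin was sonicated.

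The series carries 1 processed file, a list of 13016 peaks, and no value in it belongs to a single library. Per the submitters' processing notes, CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA and MACS2 were used on build BDGP5, and per the file headers the peaks lie on FlyBase release 5 and come from MACS. The versions of BWA and MACS2, the peak threshold, the handling of duplicate reads and the way in which the 3 replicates were combined are not given in the sources used here. Each peak in the deposited file has a start, an end and a score made by the authors' peak caller, and neither the header nor a label says whether this score is a transformed p, a transformed q or a fold enrichment. The score was therefore used only to rank and describe peaks within the list. It has 2347 different values, and 11670 peaks share their value with another peak, so ranks near the middle of the list rest on ties. No 2 peaks on the arms overlap.

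A list of this kind limits what can be measured. How the input entered peak calling is not given in the sources used here, and no input level can be given beside a peak. The depth of the libraries is unknown, so weak sites that a deeper experiment could have called cannot be told from sites without binding. Replicate error cannot be computed, and the intervals below cover counting error over peaks of 1 list only. Peaks are not independent replicates, since neighbours can come from 1 stretch of enriched chromatin.

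Peaks on the 6 main chromosome arms (X, 2L, 2R, 3L, 3R and 4) entered the comparisons, and peaks on the unplaced scaffolds U and Uextra and on the heterochromatic scaffolds (names ending in Het) were counted apart. Coordinates are 1-based on release 5. Peak position was the midpoint of the interval, because the file gives no summit. Each arm's share of peaks was tested against its share of the summed spans with a two-sided exact binomial test and Benjamini-Hochberg adjustment over the 6 arms. The span ran from the first to the last peak of an arm, since no genome of release 5 was used here. Spacing was the share of peaks, among those with a next peak on the arm, whose next midpoint lay within 5 kb. It was compared with 1000 seeded uniform placements of as many peaks within each span, and the smallest two-sided p that these can give is 0.0020. The ratio of variance to mean of counts in complete 1 Mb bins was tested in the same way. Score and width were related by Spearman's rho with 100000 permutations, whose smallest p is 1.0e-05. Regions were formed by joining peaks whose facing edges lay within 5 kb. Binomial and Poisson intervals are exact (Clopper-Pearson for shares) at 95%, and intervals of medians come from order statistics.

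Alternatives were the strongest 50% of the peaks, merging of peaks within 5 kb, distances of 2 and 20 kb, 500 kb bins and placement within 50 kb of each peak's own position. The peaks named in the text are the 10 strongest on the main arms and the strongest of each arm. Tests, alternatives and this rule were chosen before the data were examined, except where the text says otherwise. Planned tests that need a release 5 genome or annotation were not run. These are the distance of peaks to transcription start sites, location in exons, introns and UTRs, the Insv motif and other motifs, enriched 8-mers, and 14 gene lists, among them Notch target, proneural, insulator protein, Hox and haemocyte genes. The gene table at hand is of release 6, and coordinates of different releases were not mixed, so no peak is assigned to a gene.

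The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were checked on simulated data, 20 lists of 12693 peaks each. On uniform lists the spacing test called 1 of 20, the test along the arms 0 of 20, and the arm test at least 1 arm in 2 of 20. With X made 1.2 times as dense, the arm test called X in 20 of 20 lists and estimated a mean ratio of 1.2. With peaks placed in pairs, the spacing test called 20 of 20.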

Results

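Insv is a nuclear BEN domain protein that is known to act as a transcriptional corepressor in Notch signalling and to bind DNA directly. Its genomic sites were mapped by ChIP-seq in Kc167 cells, with 3 ChIP and 3 input samples, and the question was where in the genome of these cells Insv is found. The data consist of 1 list of peaks from the authors' peak caller, on FlyBase release 5, with a score per peak. Values of single libraries are not part of that list, so the comparisons below are between parts of the genome and not between samples. The depth of the libraries is unknown, and no p-value here measures variation between replicates.

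Insv peaks were found on each of the 6 main arms and were mostly narrow. The list held 13016 peaks, of which 12693 (97.5%) lay on the main arms, where they covered 10077 kb in total. The median peak on the arms was 520 bp wide (95% interval 509 to 530), with quartiles of 313 and 960 bp. The narrowest was 201 bp and the widest, on X, was 9946 bp. The authors' score had a median of 15.8 (15.5 to 15.8) and a long upper tail. Scores above 50 were given to 737 peaks (5.81%), scores above 100 to 127 peaks and scores above 300 to 8 peaks. Median scores per arm ran from 15.0 on 3L (14.5 to 15.4) to 16.3 on X (15.8 to 16.9).

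The strongest peak lay on 2R, from 10027900 to 10030247, with a score of 618.73. It stood nearly alone, with 1 other peak in its region and 3839 bp to that neighbour. The next in rank lay on X from 6736469 to 6741728, with a score of 466.32, inside a region of 40 peaks. The third lay on 2R from 17589988 to 17592506, with a score of 441.83 and in a region of 27 peaks. The fourth, on X from 17716360 to 17721766, scored 391.49 and had no other peak within 14506 bp. The fifth was the widest peak of the list, on X from 6178608 to 6188553, with a score of 371.52 and in a region of 29 peaks. Ranks 6 to 10 were held by peaks on 3R (27538378 to 27540006, score 355.11), 3L (21194381 to 21196665, score 354.3), X (15350006 to 15358576, score 304.89), 3R (24972905 to 24974388, score 253.37) and X (19047041 to 19049175, score 235.17). Thus 5 of the 10 strongest peaks were on X. The strongest peak of 2L, at 14490090 to 14491294, scored 230.86, and the strongest of chromosome 4, at 527541 to 529368, scored 69.36. Whether these peaks lie in promoters, introns or between genes was not analysed here.

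Stronger peaks were wider. With the peaks sorted by score into 4 equal groups, median width was 279 bp in the group with the lowest scores, 406 and 678 bp in the next groups and 1304 bp in the group with the highest. Across the 12693 peaks Spearman's rho between score and width was 0.77 (permutation p = 1.0e-05, the smallest that 100000 permutations can give). The relation is across peaks of 1 list, which are not independent replicates. Score and width were both set by the peak caller, and how far the calling itself ties them cannot be told from the list.

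The arms differed in how densely they carried Insv peaks. Arm 2R was the densest, with 2829 peaks or 137 per Mb of its span, against 101 per Mb on the other arms together. Arm 3L carried 2017 peaks or 82.9 per Mb against 113 per Mb elsewhere, and 2L carried 2045 peaks or 89.4 per Mb against 111 per Mb. Arm 3R had 3293 peaks (118 per Mb against 104) and X had 2490 (112 per Mb against 106). Chromosome 4, a small chromosome that is largely packed as heterochromatin, had 19 peaks. These were spread over a span of 0.615 Mb, or 30.9 per Mb against 107 elsewhere. That span begins only at 436254, while the spans of the other arms begin at or before 148930. Sequence ahead of its first peak is left out, so the density over the whole of chromosome 4 is lower than 30.9 per Mb. The ratios and tests for chromosome 4 below rest on this span.

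Against the arms' shares of the span, the exact binomial test over peaks gave adjusted p = 4.16e-43 for 2R, which held 22.3% of the peaks (95% interval 21.6 to 23.0) on 17.5% of the span. It gave 9.52e-40 for 3L, with 15.9% of the peaks (15.3 to 16.5) on 20.5% of the span, and 5.29e-20 for 2L, with 16.1% (15.5 to 16.8) on 19.3%. The adjusted p was 1.24e-10 for 3R, 3.38e-11 for chromosome 4 and 0.014 for X. Peaks lay in groups, so this test overstates the precision. With whole 1 Mb bins as units, a permutation test chosen after seeing the data kept 2R (138 ± 58.3 peaks per bin, SD over 20 bins, against 101 elsewhere, adjusted p = 0.036) and 3L (84.0 ± 61.7 over 24 bins against 114, adjusted p = 0.0495). The same permutation test did not call 2L (ratio to the other arms 0.83, adjusted p = 0.25), 3R (1.12, adjusted p = 0.38) or X (1.07, adjusted p = 0.59). It treats bins as exchangeable, but neighbouring bins were alike in places. On 3L from 4 to 19 Mb, each bin held fewer peaks than the mean of 107. This test may thus also overstate the precision, and its call for 3L lies at the threshold. Merging peaks within 5 kb into 1 can move the ratios towards 1 by itself, since a denser arm can lose more peaks to it. How large that effect is was not computed. After this merging, the exact binomial test still called 2R (ratio to the other arms 1.22, before merging 1.36, adjusted p = 0.00047) and 2L (0.87, before 0.80, adjusted p = 0.020). Merged peaks still varied between 1 Mb bins by more than placements did (ratio of variance to mean 2.37 against 0.82 to 1.64). The exact binomial test may thus overstate the precision here too. It no longer called 3L (exact binomial test, 0.94, before 0.73, adjusted p = 0.38), 3R (1.05, before 1.14, adjusted p = 0.46), X (0.96, before 1.06, adjusted p = 0.46) or chromosome 4 (0.96, before 0.29, adjusted p = 1).

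**Figure D1:**
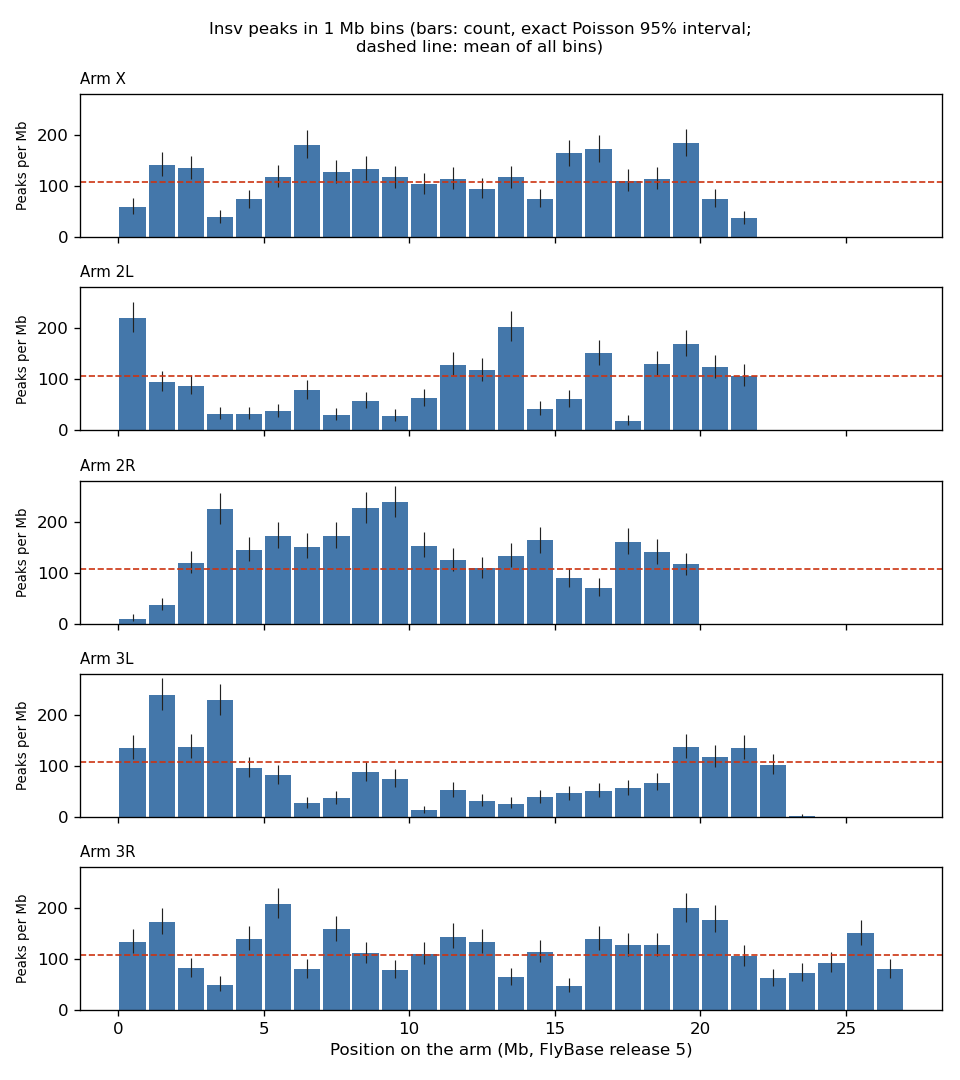
Number of Insv peaks (vertical axis, peaks per Mb) in each complete 1 Mb bin along arms X, 2L, 2R, 3L and 3R (horizontal axis, Mb on FlyBase release 5). Bars are counts with exact Poisson 95% intervals and the dashed line is the mean of all bins, 107 peaks; counts run from 1 near the end of 3L to 239 near its start.

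Within the arms, peak density varied between 1 Mb bins by more than chance placement gives. The 116 complete bins held 107 ± 55.9 peaks (SD over bins), with quartiles of 62.8 and 140. The densest bin was on 3L from 1 to 2 Mb, with 239 peaks (exact Poisson 95% interval 210 to 271). It was followed by 2R from 9 to 10 Mb with 238 (209 to 270), 3L from 3 to 4 Mb with 228 (199 to 260), 2R from 8 to 9 Mb with 226 (197 to 257), 2R from 3 to 4 Mb with 224 (196 to 255) and 2L from 0 to 1 Mb with 221 (193 to 252). On 3L the middle of the arm was sparse, with 13 peaks (6.92 to 22.2) from 10 to 11 Mb and 26 (17.0 to 38.1) from 13 to 14 Mb. On 2L the bin from 17 to 18 Mb held 19 peaks (11.4 to 29.7), while the bin from 13 to 14 Mb held 203 (176 to 233).

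The ends that face the centromere held few peaks on 2L, 2R, 3L and X and not on 3R, a pattern seen in the data and not tested. Some interior bins were about as sparse, such as X from 3 to 4 Mb with 39 peaks and 2L from 17 to 18 Mb with 19. The last complete bin of 2L, from 21 to 22 Mb, held 107. How well reads could be mapped near the centromere is not known here, so few peaks need not mean little binding. The bin of 2R from 0 to 1 Mb held 10 peaks (4.80 to 18.4), that of 3L from 23 to 24 Mb held 1 (0.025 to 5.57) and that of X from 21 to 22 Mb held 37 (26.1 to 51.0). The incomplete last bin of 2L, from 22 Mb to the last peak at 22.94 Mb, held 22 peaks. The bin of 3R from 0 to 1 Mb held 134 (112 to 159). The longest stretch with no peak ran on 3L from 23085602 to 24385597. The next lay on 2L from 17500639 to 18132060 and on X from 21261184 to 21872965. The ratio of variance to mean over all bins was 29.1, while 1000 uniform placements that kept each arm's number of peaks gave 4.67 to 5.56 (permutation p = 0.0020, the smallest these placements can give). With peaks within 5 kb merged into 1, the ratio was 2.37 against 0.82 to 1.64 in placements (permutation p = 0.0020).

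Insv peaks came in groups. For 77.5% of peaks the next peak on the arm lay within 5 kb, midpoint to midpoint, and the median distance was 1835 bp (quartiles 1010 and 4187 bp). Uniform placement put 41.2 to 43.1% of peaks within 5 kb of the next (permutation p = 0.0020, the smallest possible). Joining peaks whose facing edges lay within 5 kb gave 2606 regions. Single peaks made up 902 of these, or 7.11% of all peaks. Another 374 regions held 10 or more peaks each and together 6350 peaks, 50.03% of the total. There were 96 regions of 20 or more peaks, and no placement without overlap gave more than 1.

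Regions and peak-free stretches were formed and singled out after seeing the data. The region with the most peaks was on 3L from 3354704 to 3472807, where 71 peaks covered 51.7% of 118 kb. Next were 2L from 467753 to 579138 with 68 peaks over 111 kb (70.4% covered), X from 19492197 to 19612674 with 60 peaks over 120.5 kb (59.6% covered) and 3R from 1425636 to 1503361 with 53 peaks over 77.7 kb (41.4% covered). The first 3 of these had highest scores of 145.97, 180.62 and 107.19, and the region on 3R had none above 44.6. The region on X from 6696850 to 6765137 held 40 peaks and included the peak of rank 2.

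**Figure D2:**
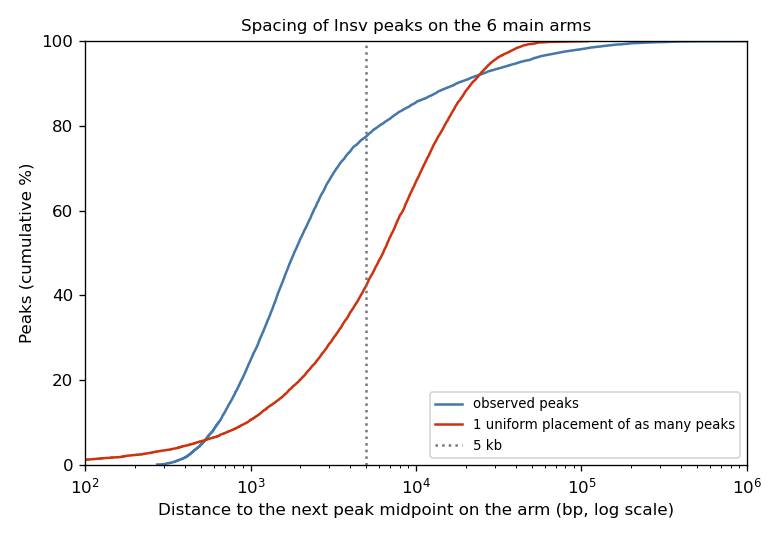
Cumulative share of Insv peaks (vertical axis, %) against the distance from a peak's midpoint to the next on the arm (horizontal axis, bp, log scale), for the observed peaks and for 1 uniform placement of as many peaks. At 5 kb, the dotted line, the observed curve stands at 77.5% and uniform placements average 42.3%.

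Outside the main arms the list held 323 peaks. Uextra, the collection of short sequences that could not be placed in the assembly, carried 300 of them, and the remaining 23 were on U and the heterochromatic scaffolds. The peaks on Uextra had a median score of 47.7 (95% interval 42.9 to 53.5) and a median width of 590 bp (561 to 616), compared with 15.8 and 520 bp on the main arms. The score difference of 31.9 was larger than in any of 100000 permutations (two-sided permutation test over peaks, added after seeing the data, p = 1.0e-05, the smallest they can give). The peaks on U and the heterochromatic scaffolds had a median score of 20.9 (15.4 to 29.3) and a median width of 320 bp (239 to 435).

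**Figure D3:**
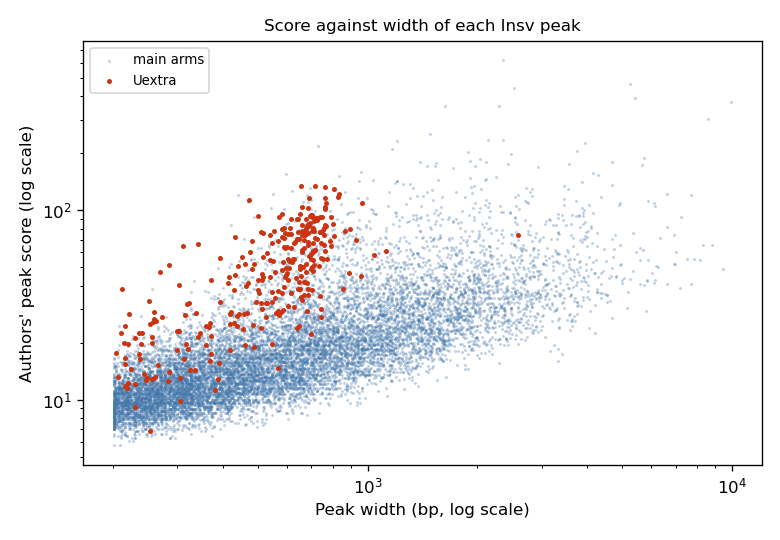
The authors' peak score (vertical axis, log scale) against peak width (horizontal axis, bp, log scale), 1 point per peak, for the main arms and for Uextra. Score increases with width on the main arms (Spearman's rho 0.77), and the Uextra peaks, median score 47.7, lie above most main-arm peaks of equal width.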

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

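The tests in this part were chosen after the scores on the scaffolds had been seen. Peaks outside the main arms belong to no planned comparison, and 3 scaffolds carried more than the 3 that a count of 0 allows. Uextra held 300 peaks, U held 9 and 3LHet held 8.

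The peaks on Uextra stood apart by their scores, with a median of 47.7 against 15.8 on the main arms. Width as the whole cause was argued against, because the Uextra median was 32.17 higher than that of 1500 main-arm peaks matched on width (permutation p = 1.0e-05, the smallest possible). The permutation tests in this paragraph treat peaks as independent and do not use the matching on width. A general rise of scores on sequence outside the arms stays open. The 23 peaks on U and the heterochromatic scaffolds had a lower median score, 20.93, but were narrower, at a median of 320 bp against 590 bp on Uextra. At equal width their median score differed by -3.34 from that of 23 Uextra peaks (permutation p = 0.38) and was 9.38 above that of 115 main-arm peaks (permutation p = 2.0e-05), and so few peaks cannot show whether the rise on Uextra is larger. Also open are sequence present in the cells in more copies than in the assembly, sequence from another source in the sample, and an input estimate that is poor on short sequences, and none of these was tested. No biological explanation was tested, since the samples do not differ in a way that bears on the scaffolds.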

How the results depend on the processing

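The test of arms with 1 Mb bins as units and those on merged peaks within 1 or 2 kb, on placement without overlap and on the strongest peaks were added after seeing the data. Among the strongest 50% of the peaks the median width was 922 bp instead of 520 bp. The ratio of density on an arm to that on the other arms lost its call for X (1.07), 2L (0.83) and 3R (1.12) with bins as units. With peaks within 5 kb merged it lost its call for 3L (0.94, main 0.73), 3R (1.05, main 1.14) and chromosome 4 (0.96, main 0.29). X reversed to 0.96. Both settings leave fewer units to test. Under merging the ratios of 3L, 3R and chromosome 4 moved towards 1, and that of X passed below 1. Joining alone can move ratios towards 1, since a denser arm can lose more peaks to it. How large that effect is was not computed. The move alone thus shows neither that the arms differ less nor that joining accounts for it. 2L kept its call under that merging (0.87, main 0.80), by a test that treats merged peaks as independent. 2R kept its direction and its call under the 3 alternatives run, with ratios of 1.22 to 1.36. The excess of close neighbours over placements, 35.2 percentage points, kept its call under each of 7 alternatives. It ran from 2.60 points at 20 kb, where nearly all placed peaks have a neighbour, to 35.8 points among the strongest 50%. Placement without overlap and the merged settings were measured between facing edges, the others between midpoints. The ratio of variance to mean kept its call, at 2.37 to 20.9, as did the relation of score and width, at a rho of 0.54. No denominator other than the spans and no other score was tried, since no genome of release 5 was used and the file holds 1 score. The ratios for chromosome 4 rest on a span that leaves out the sequence ahead of its first peak. No setting that needs a genome or annotation was run. No paired analysis was possible because the peak list has no values per library. Depth is unknown and limits which weak peaks were called.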

Other observations

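All tests in this part were chosen after seeing the data, except the placement within 50 kb of each peak, which was planned. The strongest peaks were compared for their share on X, which was picked because 5 of the 10 strongest lay there. No other arm was tested. Those 10 peaks are part of every set of strongest peaks below, so the p-values for X are not independent of that choice and are too small. The adjustment over 3 comparisons does not cover the choice of X among the arms. Whether the excess on X holds without those 10 peaks was not tested. Of the 100 strongest, 30 were on X (30.0%, exact 95% interval 21.2 to 40.0), where 19.5% of the other 12593 peaks lay (Fisher's exact test, two-sided, p = 0.011, adjusted p = 0.024 over 3 comparisons). These 30 lay in 14 different 1 Mb bins, and the test treats them as independent, so it overstates the precision. The excess on X was 8.01 percentage points among the strongest 200 (Fisher's exact p = 0.0068) and 4.56 among the strongest 500 (p = 0.013), and 8.42 among the strongest 50, where it was not past the threshold (p = 0.15). Peaks that stood alone were also more frequent among the strongest 100, at 14.0% (7.87 to 22.4) against 7.05% of the others (Fisher's exact p = 0.016, adjusted p = 0.024). Such peaks made up 12.5% of the strongest 200 against 7.02% of the others (Fisher's exact p = 0.0052) and 12% of the strongest 500 against 6.91% (p = 5.58e-05). Among the strongest 50 they made up 14.0% against 7.08%, which was not past the threshold (Fisher's exact p = 0.087). The sets of strongest peaks are nested, so their p-values are not separate evidence. The strongest 100 were also wider, at a median of 1926.5 bp against 520 bp on the arms. No comparison at equal width was made for peaks that stood alone.

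The grouping of peaks may reflect several processes. If the caller had only split broad stretches into pieces at most 1 kb apart, joining peaks within 1 kb should have removed the excess. Yet 55.6% of the 5867 joined regions still had the next within 5 kb, measured between facing edges. Placements that respect the same gap and widths gave 19.7 to 23.0%. Splitting into pieces with wider gaps is not covered and stays open, since the upper quartile of the gaps between facing edges was 3311 bp. If only density over stretches much longer than 50 kb varied, moving each peak by up to 50 kb either way should have kept the share of close neighbours, but the highest of 1000 such placements was 60.7% against 77.5% observed. Broad density can still account for a part, since the excess was 17.6 points over the 50 kb placements and 35.2 points over uniform ones. Those 2 values are from midpoints. Between facing edges, the excess was 34.4 points without joining, 34.2 after joining within 1 kb and 25.1 after joining within 2 kb. The copy number of stretches much longer than 50 kb is argued against as the whole cause by the 50 kb placements, since those keep such density. Uniform and 50 kb placements both keep each arm's number of peaks, so they do not test the copy number of whole chromosomes. The copy number of shorter stretches and the location of genes and of open chromatin stay open and untested.

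The place of the strongest peaks relative to large regions depended on how regions were formed. With peaks joined by midpoints, 28.0% of the 100 strongest lay in regions of 10 or more peaks against 44.5% of the others (Fisher's exact p = 0.00082). With facing edges, the shares were 42.0% and 50.1%, a difference of -8.09 percentage points (Fisher's exact p = 0.11), and against all weaker peaks the difference was -2.04 for the strongest 50 (p = 0.78), -2.06 for the strongest 200 (p = 0.57) and -2.53 for the strongest 500 (p = 0.27). The first contrast may thus come from wide peaks, whose midpoints lie far from their neighbours, and whether that is the whole cause cannot be told from 100 peaks. A different comparison, with facing edges and at equal width, put the strongest 100 in large regions less often than 500 weaker peaks (42.0% against 64.8%, a difference of -22.8, Fisher's exact p = 2.84e-05). These weaker peaks were themselves in large regions more often than weaker peaks in general, so the comparison does not bear on midpoints. The difference was -13.5 for the strongest 200 (Fisher's exact p = 0.00050) and -14.4 for the strongest 50 (p = 0.081). It was -12.8 for the strongest 500 (Fisher's exact p = 1.31e-07), where the matching was incomplete, with median widths of 1642.5 bp for the strongest and 1537 bp for the weaker peaks. The Fisher's exact tests on large regions treat peaks as independent, although peaks of 1 region share its size, so they overstate the precision. They also do not use the matching on width.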
